A study of Papio papio with 23 samples.

How the data were processed

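Gene expression was measured in peripheral whole blood of Papio papio baboons on human Agilent single-colour arrays, 1 array per sample and 23 arrays in all. Per the labels' protocols, 2.5 ml of blood was drawn into PAXgene tubes, total RNA was isolated, and 100 ng was labelled with Cy3. The arrays fall into 5 groups by the titles. Group H0 holds 5 baboons before irradiation. Groups H1-2 and H2-3 are named for the category of haematological acute radiation syndrome (HARS, the loss of blood cells that follows irradiation) that a baboon developed later, and hold 4 and 5 baboons, each sampled on day 1 and on day 2. The labels give equivalent whole-body doses of 2.5 or 5 Gy, delivered to the total or part of the body, for the study as a whole and not for single animals, so dose was not analysed here. The titles number the baboons within a category on both days. Whether the H0 baboons are the same animals as the irradiated ones is not given in the sources used here.

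Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 10.7.3.1, and the deposited scanner files hold spot intensity on a linear scale with the background already subtracted. Each array has 62976 spots, and 50599 different probes remained after control spots were left out. Probe positions in the files are on the human build hg19. The probes were designed for human transcripts and hybridised with baboon RNA, so a sequence difference under a probe can lower its signal. The deposited value table holds log2 values of the same arrays with 39726 probes, of which 39637 matched a probe of the scanner files. Set against the scanner intensities, each column correlated with its own array at 0.9982 to 0.9999 with a positive slope, which settled its scale and direction. The column medians were 4.706 or 4.707 and the distributions nearly identical. How its probes were selected and its exact centring stay unknown, and it served as an alternative.

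For the main values, log2 of the processed signal was taken and the spots of a probe were then averaged. Spots flagged as outliers were left out where other spots of the probe remained. The array's 75th percentile over non-control probes was subtracted. A probe was kept when it was well above background on at least 4 arrays, which left 27215 probes. Of 36337 gene names, 9562 had over 1 probe, and the kept probe with the highest mean over all arrays stood for its gene, which gave 21130 genes, 14074 of them with a gene symbol. On single arrays 41.4 to 51.3% of the probes were well above background, and the 75th percentile of the signal was 80.9 to 156.4. The number of arrays limits the precision. For a probe at background on every array of a group, a change is given as at least so many fold, with the mean of the brighter group set against a floor, per array the higher of the lowest signal well above background and the probe's own signal. Where only some arrays of the dimmer group were well above background, their number is given. A fold with the floor takes the same floor on the other arrays of that group. Genes were ranked for naming on the fitted change, so where a signal was at background a gene's place among the largest changes was not measured.

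Groups were compared with limma 3.58.1 in R 4.3.3 (with data.table version 1.17.8 and statmod 1.5.0), in a single fit with 5 group means, moderated statistics and two-sided tests with Benjamini-Hochberg adjustment at 0.05. This main fit has no term for the baboon, so it leaves out the pairing of the days. Alternative fits took the baboon as a block. An additional fit averaged the 2 arrays of each irradiated baboon first. The 21 gene lists were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. Each was tested again with the correlation estimated from the data and with fry, which asks whether the genes of a list move, on balance, in the same direction. A median beside a list is the median log2 fold change of its tested members. The p53 list shares 1 tested gene with another list, the naive lymphocyte list 2, the glucocorticoid list 2 and the B cell, T cell, NK and neutrophil lists 0. The text names, in each comparison with the H0 group or between categories, the 5 genes with a symbol that rose most and the 5 that fell most among those past the threshold (3 and 3 between days), the 2 members of each list with the smallest p over the 5 groups, and a set of common blood and radiation markers. MS4A1 and ARG1, which belong to that set, were well above background on 1 of 23 arrays and were not tested. Some genes that this rule names are not reported here. A gene named outside this rule is said to have been chosen after its values were seen. Groups, designs, gene lists, the naming rule and the alternative settings were set before the data were examined, except the settings said to have been chosen after seeing the data.

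The computation was tested on simulated data in which 200 of 21130 genes were changed. For H1-2 day 1 against H0 it recovered 34% of genes changed by 1 and 78% of genes changed by 2 on the log2 scale. For H2-3 day 1 against H0 the shares were 46% and 89%, for H2-3 against H1-2 on day 1 27% and 80%, and for day 2 against day 1 in H2-3 35% and 89%, with 0 genes called in the wrong direction. In the same order, 1 of 113, 10 of 145, 3 of 110 and 6 of 130 calls were of unchanged genes. The simulated arrays were drawn independently, with no effect of slide, scan day or baboon, so these shares do not cover such effects.

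The arrays lay on 7 slides and were scanned on 3 days. Scan day 1 holds all day 1 arrays and H0 replicates 3 to 5, scan day 2 all day 2 arrays, and scan day 3 H0 replicates 1 and 2. Comparisons of day 2 with H0 or with day 1 can therefore not be told apart from scan day. On slides 3 and 4 (day 1) and slides 5 and 6 (day 2) both HARS categories are present, and slide 1 holds an H0 and an H2-3 array. The titles give the same animals on both days, so their numbers pair the arrays of a category across days. Deviations from the group means of the same baboon on both days correlated across genes at 0.38, 0.39, 0.16 and 0.06 in H1-2 and at 0.05, 0.44, 0.16, 0.13 and 0.33 in H2-3, against means of -0.08 and -0.05 for different baboons. The best match was the same number for H2-3 baboons 2 to 5, but another number for H2-3 baboon 1 and H1-2 baboons 1 to 4. The pairing therefore rests on the titles. Arrays of a group correlated at 0.936 to 0.981, and none were duplicates.

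Results were recomputed with quantile normalisation, array median scaling and normexp background correction with an offset of 50, with no filter on dim probes or a filter at 12 arrays, and with the mean of a gene's probes, or the deposited values. Other fits used a variance trend with robust shrinkage, array weights, the baboon, slide or scan day as a block, a fit with only the compared groups, the replicate number as a block, other set tests, and leaving out each array in turn. A 75th percentile over probes detected on all arrays, fits within single slides and the replicate block with an estimated correlation were chosen after seeing the data. The qRT-PCR stage named in the study design was not analysed here.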

Results

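Blood was sampled from baboons before irradiation (H0, n = 5) and on days 1 and 2 after gamma irradiation of animals that later developed HARS of category H1-2 (n = 4 on each day) or the more severe category H2-3 (n = 5 on each day). The study's aim was to find transcripts that, in the first 2 days, mark the HARS that follows. The share of probes well above background was 49% ± 2.5 (SD, n = 5) in H0. It was 46.5% ± 0.9 (n = 4) and 48.4% ± 2.3 (n = 4) in H1-2 on days 1 and 2, and 46.2% ± 2.8 (n = 5) and 48.7% ± 2.3 (n = 5) in H2-3. Levels below are log2 signals relative to the array's 75th percentile, and changes are log2 differences ± standard error. They are levels in whole blood, so a change in the mix of cells and a change within cells cannot be told apart. All adjusted p-values are from limma.

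On day 1 in H1-2, 13 of 21 neutrophil markers and 9 of 20 inflammatory genes rose against H0, while 12 of 19 NK and 7 of 17 T cell markers fell. MARCO, a scavenger receptor of macrophages, was at background on all 5 H0 arrays and rose at least 11.1-fold (adjusted p = 0.0141), above every H0 array on 4 of 4 arrays. CD177, a surface protein of neutrophils, rose 11.9-fold (3.58 ± 0.72, adjusted p = 0.0141), with 3.79 and 1.26 for its other probes, and HSPB1, a small heat shock protein, rose 8.1-fold (3.02 ± 0.47, adjusted p = 0.0104). CD3G, a chain of the T cell receptor complex, fell 4.32-fold (-2.11 ± 0.42, adjusted p = 0.0141) and was below every H0 array on 4 of 4 arrays. FGFBP2 and the granzyme GZMH, both products of cytotoxic lymphocytes, fell 7.67-fold and 5.47-fold (adjusted p = 0.0479 and 0.0202). The naming rule also took SLC26A9, an anion transporter at background in H0, which rose at least 2.89-fold, and TMEM44, which rose 8.94-fold with 1 H0 array at 1.93 against -2.21 to -1.07 on the other 4. FRMD6 (8.13-fold; well above background on 2 of 4 H1-2 arrays, and 5.81-fold with the floor on the others), HTRA1 (5.45-fold) and MTX3 (at least 1.68-fold) fell.

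Of 21 mature neutrophil markers 13 rose and 0 fell on day 1 in H1-2 (20 rose adjusted over the list alone; median 1.53), among them the chemokine receptor CXCR1 (1.67 ± 0.39) and the G-CSF receptor CSF3R (1.32 ± 0.32). Of 19 NK and cytotoxic markers 12 fell (17 adjusted over the list alone; median -1.83), with CTSW at -1.87 ± 0.44 and GZMK at -1.75 ± 0.46. Of 17 T cell markers 7 fell (15 adjusted over the list alone; median -1.54). Of 20 innate inflammatory genes 9 rose (13 adjusted over the list alone; median 1.5), including the inflammasome gene NLRC4 (1.71 ± 0.41) and the IgA receptor gene FCAR (2.11 ± 0.53). Camera called these 4 lists, with adjusted p = 0.363 to 0.364 with an estimated correlation. It also called, with medians in brackets, monocyte markers (0.76; 3 of 14 rose), granule genes of immature neutrophils (0.74; 3 of 16 rose) and glucocorticoid-responsive genes (0.89; 4 of 10 rose, among them CD163 and TSC22D3). Further calls were interferon-stimulated genes (-0.61; 5 of 22 fell, among them ISG15 and USP18), DNA repair genes (-0.47; 5 of 18 fell, among them PARP1, and XRCC5, named after its value was seen, rose) and ribosomal proteins (-0.56; 6 of 79 fell). Naive lymphocyte markers (-1.10; 1 of 7 fell), eosinophil and basophil markers (-0.96; 0 of 8 passed) and B cell markers (-0.77; 0 of 19 passed) were called as well. For these 3 calls and the 6 before them the estimated correlation gave adjusted p = 0.364 to 0.552. The mean level of the B cell markers was 1.16 ± 1.18 (SD, n = 4), against 1.86 ± 0.23 (SD, n = 5) in H0. Averaged over both days it was 0.22 and -0.03 in H1-2 baboons 1 and 2 but 2.42 and 2.32 in baboons 3 and 4. Adjusted over the list alone, 7 monocyte and 8 granule genes rose and 7 interferon-stimulated, 7 DNA repair and 37 ribosomal genes fell. Among cell cycle genes TYMS, named likewise, rose by 2.02. Camera also called the list of p53 targets and radiation response (median 0.53; adjusted p = 0.0277, and 0.534 with an estimated correlation). In it 2 of 28 genes rose, including the DNA damage sensor DDB2 (1.16 ± 0.35), and the polo-like kinase PLK2 fell (-1.46 ± 0.40). CDKN1A, the p53-induced cell cycle inhibitor, was at 1.61 (adjusted p = 0.069) and FDXR, a ferredoxin reductase used as a radiation marker, at -0.80 (adjusted p = 0.0546). CDKN1A was well above background on 1 of 5 and TYMS on 2 of 5 H0 arrays, and CTSW and USP18 on 2 and PLK2 on 3 of 4 H1-2 arrays. Plasma cell markers (-0.12), erythroid (-0.04), platelet (0.48), cell cycle (-0.47), MHC class II (0.04), WNT pathway (0.09) and immediate early and heat shock genes (0.70; HSPA1A rose) were not called. The MHC class II and WNT medians turned negative under other scalings, and their means were -0.09 and -0.15.

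Of the 21 lists camera called 14 for H1-2 on day 1 at its preset correlation and 0 with an estimated correlation, and fry called 8. In all, 1816 genes changed in H1-2 on day 1, 883 higher and 933 lower, 1100 of them at least 2-fold. The higher share, 48.6%, was 34.5% with quantile normalisation (726 higher, 1378 lower), 34.6% in the deposited table (736 and 1391) and 32.4% with the percentile over probes detected on all arrays (751 and 1569). With slide as a block 9 genes passed, and with scan day as a block, which leaves 3 H0 arrays in the comparison, 4 passed. With those blocks in turn the medians of the neutrophil list were 2.31 and 1.24, of the T cell list -3.10 and -1.49, of the NK list -3.28 and -1.67, of the inflammatory list 1.74 and 0.91 and of the p53 list 0.40 and 0.51. In the same order they were -1.28 and -0.95 for B cell, -2.66 and -1.19 for naive lymphocyte, 0.77 and 0.58 for monocyte and -2.21 and -0.78 for eosinophil and basophil markers. For granule genes they were -0.10 and 0.67, for interferon-stimulated genes -1.55 and -0.84, for glucocorticoid-responsive genes 1.03 and 0.57, for DNA repair genes -0.81 and -0.68 and for ribosomal proteins -0.19 and -0.46. No slide holds both groups, so the fit with slide as a block links them through slide 1 alone, with 1 H0 array and 1 H2-3 array. A fit with these 2 groups alone called 211 genes, and the count was 497, 3105, 817 or 543 without H0 replicate 1, 3, 4 or 5 and 4, 402 or 891 without H1-2 replicate 1, 2 or 4.

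On day 2 in H1-2, limma called 0 genes against H0. AEN, an apoptosis-enhancing nuclease induced by p53, was at 2.3 (adjusted p = 0.0761), with 3 of 5 H0 arrays well above background. MARCO, well above background on 2 of 4 H1-2 arrays and on 0 of 5 in H0, was at least 3.21-fold higher but did not pass (adjusted p = 0.315). At an unadjusted p under 0.05 there were 2228 genes, against 1056 expected by chance. Among the gene lists, platelet and megakaryocyte genes had a median of 1.28, with 11 of 15 higher adjusted over the list alone. The p53 list had a median of 0.42, with 6 of 28 higher adjusted over the list alone. Camera called both, with adjusted p = 0.401 with an estimated correlation. Camera also called NK (-0.75, adjusted p = 0.608 with an estimated correlation), B cell (-0.62), T cell (-0.39), monocyte (0.36), neutrophil (0.42), erythroid (-0.65), interferon-stimulated (-0.29) and immediate early genes (0.53), for which the estimated correlation gave adjusted p = 0.819. No member of any list passed over all genes, and fry called 0 lists. The mean level of the B cell markers was 1.31 ± 1.48 (SD, n = 4), against 1.86 ± 0.23 (SD, n = 5) in H0. Averaged over both days it was 0.22 and -0.03 in H1-2 baboons 1 and 2 but 2.42 and 2.32 in baboons 3 and 4. The lower B cell level was therefore not shared by all 4 baboons. Granule genes, not called, had a median of 0.20 and a mean of -0.20. Array weights gave 33 genes, and the count was 2, 4 or 6 without H0 replicate 3 or H1-2 day 2 replicate 3 or 4.

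**Figure D1:**
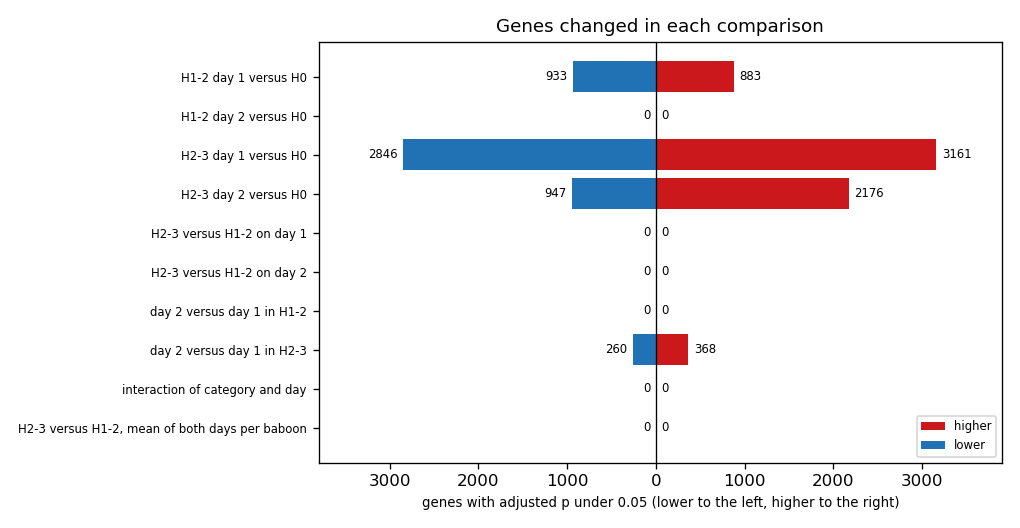
Number of genes with an adjusted p under 0.05 in each comparison (horizontal axis, genes; red bars to the right are higher and blue bars to the left lower in the group named first). The longest bars are those of H2-3 on day 1 against H0 (3161 higher, 2846 lower), and 6 comparisons have 0 genes.

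On day 1 in H2-3, 16 of 19 B cell, 15 of 17 T cell and 17 of 19 NK markers fell against H0, while 20 of 21 neutrophil, 11 of 14 monocyte and 15 of 20 inflammatory genes rose. VPREB1, the surrogate light chain of precursor B cells, fell 28.5-fold (-4.83 ± 0.91, adjusted p = 0.000625) and 10.3-fold with the floor, although 1 array, the only 1 of 5 on which it was well above background, stood at -1.19 against -5.12 to -4.36 on the other 4. The B cell kinase BLK fell 20.7-fold (-4.37 ± 0.65, adjusted p = 0.000127), well above background on 4 of 5 arrays. KLRF1, a receptor of NK cells, and FGFBP2 fell 18.1-fold and 18-fold, each 10.8-fold with the floor, and were well above background on 1 of 5 and 2 of 5 arrays. WNT3, a WNT ligand, fell 31.2-fold (-4.96 ± 0.84, adjusted p = 0.000293). MARCO rose at least 38.1-fold (adjusted p = 7.08e-05), ADAMDEC1, a metalloproteinase made by macrophages and dendritic cells, 32.3-fold (5.01 ± 0.68, adjusted p = 7.44e-05), CD1A, a lipid antigen-presenting molecule, 15.9-fold, CD177 15.5-fold and the carboxylesterase pseudogene CES1P2 14.7-fold. In H0, ADAMDEC1 was well above background on 1 of 5 arrays and CD1A and CES1P2 on 3 of 5, and with the floor on the others the folds were 16.5, 14.3 and 9.12. The MARCO probe lies on hg19 chromosome 2 at 119751977 to 119752036 and the WNT3 probe on chromosome 17 at 44841704 to 44841763.

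Of 19 B cell markers 16 fell on day 1 in H2-3 (17 adjusted over the list alone; median -2.50), of 17 T cell markers 15 fell (median -2.50) and of 19 NK and cytotoxic markers 17 fell (18 fell and 1 rose adjusted over the list alone; median -2.54). CD3G fell by 3.25 ± 0.39, GZMK by 3.34 ± 0.43, CTSW by 3.14 ± 0.41 and UBASH3A by 2.76 ± 0.41 on the log2 scale. CD3E was at 0.01 (adjusted p = 0.975) and the T cell kinase gene LCK, looked at after its value was seen, rose by 1.04 (adjusted p = 0.00352). Of 7 naive lymphocyte markers 5 fell (median -2.54), including the lymph node homing receptor CCR7 (-3.42 ± 0.69), TCF7 and BACH2. Of 8 plasma cell markers 4 fell, including MZB1 and TXNDC5, and 1 rose (median -0.80). Of 23 cell cycle genes 13 fell (15 adjusted over the list alone; median -1.14), among them the replication helicase subunit MCM4 (-2.07 ± 0.37) and the spindle checkpoint kinase BUB1, which fell at least 2.5-fold to background. The thymidylate synthase gene TYMS and the mitotic kinase gene AURKA, named after their values were seen, rose by 2.35 and 0.80. Of 18 DNA repair genes 10 fell (median -0.60), including PARP1 (-2.24 ± 0.32). The adjusted p was 0.178 with an estimated correlation for each of these 7 lists. On these H2-3 arrays CTSW was well above background on 1 of 5, MCM4 on 3 of 5 and TCF7 and BACH2 on 4 of 5, and TYMS on 2 of 5 in H0.

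Of 21 mature neutrophil markers 20 rose (median 1.87; CXCR1 2.33 ± 0.37), and of 14 monocyte markers 11 (median 1.31; CD68 1.82 ± 0.32 and FCN1 1.59 ± 0.29). Of 20 innate inflammatory genes 15 (18 adjusted over the list alone; median 1.68) rose, and of 16 granule genes 8 rose (9 adjusted over the list alone; median 1.23; RNASE3 2.49 ± 0.46). The adjusted p was 0.178 for the first 2 lists, 0.249 for the inflammatory and 0.343 for the granule genes with an estimated correlation. In the p53 list 15 of 28 genes rose (16 adjusted over the list alone; median 0.83; adjusted p = 0.364 with an estimated correlation). CDKN1A was at 2.91 ± 0.52 (adjusted p = 0.000456, above all H0 arrays on 5 of 5 arrays), with AEN at 1.65 ± 0.39, DDB2 at 1.45 ± 0.33 and MDM2, the p53 ubiquitin ligase, at 0.64 ± 0.23. Against the direction of the list, FDXR fell by 0.99 ± 0.24 (adjusted p = 0.00425) on the log2 scale and was below every H0 array on 5 of 5 arrays. PLK2 fell by 1.93 ± 0.37 and the translesion polymerase gene POLH, named after its value was seen, by 0.95. CDKN1A was well above background on 1 of 5 and AEN on 3 of 5 H0 arrays, FOSB on 4 of 5 in H0, and PLK2 and POU2AF1 on 4 of 5 H2-3 arrays. BAX was at 0.52 (adjusted p = 0.276) and PCNA at 0.58 (adjusted p = 0.126). Of 22 interferon-stimulated genes 7 fell (median -0.45; adjusted p = 0.364 with an estimated correlation), among them ISG15 (-1.23 ± 0.19) and USP18 (-2.45 ± 0.38; well above background on 1 of 5 H2-3 arrays, and 5.48-fold lower or 3.23-fold with the floor). Of 10 glucocorticoid-responsive genes 4 rose (median 0.70; adjusted p = 0.376 with an estimated correlation). Of 79 ribosomal proteins 17 fell, 4 adjusted over the list alone (median -0.48; adjusted p = 0.397 with an estimated correlation). Against the direction of this list RPS27L rose by 1.23 (adjusted p = 0.00394). RPS27L also belongs to the p53 list, whose direction it followed. Other members against the direction of their lists were XRCC5 (1.19, adjusted p = 0.00035) among DNA repair genes, XBP1 (0.54) among plasma cell markers and HSPH1 (-1.07, adjusted p = 0.0302) among immediate early genes. In the WNT list 5 of 18 genes fell (WNT3, TCF7, LEF1, WNT7A and AXIN2) and 2 rose (GSK3B by 0.67 and LRP5, well above background on 3 of 5 H0 arrays, by 0.70). Of these, all but RPS27L, WNT3 and TCF7 were named after their values were seen. Eosinophil and basophil markers (-0.54; SIGLEC8 rose), erythroid (-0.27), platelet (0.58; GP1BB, named likewise, rose), MHC class II (0.02; 2 of 11 fell), WNT pathway (0.17) and immediate early genes (0.93; 5 of 10 rose, among them HSPA1A and FOSB, and 1 fell) were not called. The MHC class II and WNT medians turned negative under other scalings, and their means were -0.47 and -0.52. HLA-DOA and HLA-DOB fell by 2.06 ± 0.41 and 1.83 ± 0.43 on the log2 scale. A second probe of HLA-DOA gave 0.32, and a second probe of POU2AF1, a B cell transcription co-activator that fell by 4.15 ± 0.60, gave 0.17. Other probes also differed in size, with 4.34 and 0.79 for CD177 (3.95 with the probe used), -2.76 for KLRF1 (-4.18), -0.51 for MZB1 (-3.08) and 1.4, 1.67 and 1.48 for MDM2.

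**Figure D2:**
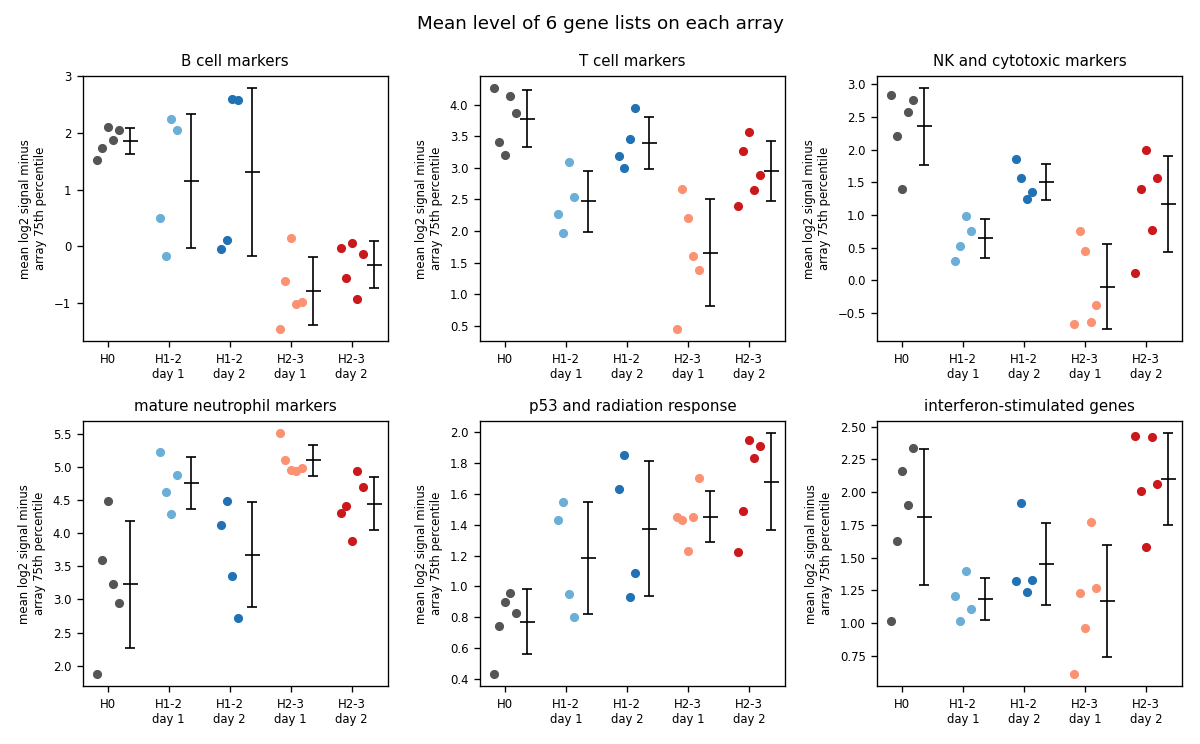
Mean level of the tested members of 6 gene lists (vertical axis, log2 signal minus the array's 75th percentile), with a point per array in each of the 5 groups and bars for the mean ± SD. Against H0 the B cell median fell by 2.50 on the log2 scale on day 1 and by 2.17 on day 2 in H2-3, and the neutrophil median was 1.87 and 1.21 higher.

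Of the 21 lists camera called 15 for H2-3 on day 1 at its preset correlation and 0 with an estimated correlation, and fry called 15. In H2-3 on day 1, 6007 genes changed, 3161 higher and 2846 lower, 3409 of them at least 2-fold. The higher share was 52.6%, and 34.8% with the percentile over probes detected on all arrays (2051 higher, 3836 lower), a scaling that lowered the median of all genes by up to 0.19, from a median of 0.14 to -0.05 here. With scan day as a block 4366 genes passed, with slide as a block 1112, and within slide 1 2347. Slide 1 is the only slide with both groups and holds 1 array of each, so both of the latter rest on the same difference of 1 array against 1. Their spread comes from the other arrays, and the lone arrays are assumed to vary like these. With scan day as a block and in that difference the medians were -2.61 and -3.28 for B cell, -2.57 and -4.09 for T cell and -2.37 and -3.62 for NK markers. In the same order they were 1.64 and 2.69 for neutrophil markers, 1.05 and 1.27 for monocyte markers and 0.66 and 0.89 for the p53 list. Naive lymphocyte markers were at -2.63 and -3.84, plasma cell markers at -0.85 and -1.64, granule genes at 0.87 and 0.60 and inflammatory genes at 1.24 and 2.02. Interferon-stimulated genes were at -0.84 and -1.5, glucocorticoid-responsive genes at 0.42 and 0.62, cell cycle genes at -1.39 and -1.95, DNA repair genes at -0.76 and -0.87 and ribosomal proteins at -0.31 and -0.13.

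On day 2 in H2-3, 16 of 19 B cell markers fell against H0, and 12 of 28 genes of the p53 list and 6 of 15 platelet genes rose. VPREB1, whose probe was at background on all 5 arrays of this group, fell at least 15.5-fold (adjusted p = 0.00866), and another probe was well above background on 1 of 5. WNT3 fell 15.3-fold, FCRL2, an Fc receptor-like protein of B cells, 11.2-fold, the B lineage transcription factor EBF1 8.99-fold and the sulfotransferase HS3ST1 8.9-fold. EBF1 was well above background on 3 of 5 and HS3ST1 on 4 of 5 of these arrays, with 6.94-fold and 8.32-fold with the floor on the others. A second probe of FCRL2 gave -0.50 against -3.49 on the log2 scale, and a second probe of POU2AF1 0.01 against -2.17. Of 19 B cell markers 16 fell (19 adjusted over the list alone; median -2.17). MARCO rose at least 16.9-fold (adjusted p = 0.0031), WTH3DI at least 5.77-fold and ID1, an inhibitor of DNA binding by helix-loop-helix factors, at least 3.6-fold. Rises were also seen for the bradykinin receptor BDKRB2 (12.2-fold) and the myosin chaperone UNC45B (11.9-fold). In H0, BDKRB2 was well above background on 2 of 5 arrays (11.2-fold with the floor) and UNC45B on 1 of 5 (4.08-fold with the floor), an array at -2.58 against -5.49 to -4.76 on the other 4. In the p53 list 12 of 28 genes rose and 0 fell (18 adjusted over the list alone; median 0.86), with AEN at 2.43 ± 0.39, CDKN1A at 2.16 ± 0.52, DDB2 at 1.96 ± 0.33 and PCNA at 1.23 ± 0.28. FDXR was at -0.53 (adjusted p = 0.127).

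Of 15 platelet and megakaryocyte genes 6 rose on day 2 in H2-3 (13 adjusted over the list alone; median 1.53), including the platelet integrin ITGA2B (1.73 ± 0.43), while PF4 was at 0.84 (adjusted p = 0.182). Of 21 neutrophil markers 10 rose (13 adjusted over the list alone; median 1.21), of 14 monocyte markers 7 (8 adjusted over the list alone; median 0.92) and of 20 inflammatory genes 8 (10 adjusted over the list alone; median 1.11). Of 10 immediate early and heat shock genes 4 rose (6 adjusted over the list alone; median 1.01; FOSB 2.18 ± 0.42), as did 4 of 10 glucocorticoid-responsive genes (median 0.79). Of 17 T cell markers 3 fell (6 adjusted over the list alone; median -0.86), of 19 NK markers 5 (10 adjusted over the list alone; median -1.28) and of 7 naive lymphocyte markers 2 (median -1.16). Camera called all of these lists; the adjusted p was 0.364 for T cell and 0.353 for the other lists of this day named so far with an estimated correlation. It also called erythroid genes (-0.79; IFIT1B fell), ribosomal proteins (-0.33; 0 of 79 fell) and cell cycle genes (-0.52; 2 of 23 fell, MKI67 and CDK1, named after their values were seen), with adjusted p = 0.47, 0.47 and 0.393 with an estimated correlation. Against the direction of their lists TYMS (2.25), XRCC5 (0.92) and, among ribosomal proteins, RPS27L (1.22) rose. ELANE, at background on all 5 arrays of this group, fell at least 1.51-fold against its list (adjusted p = 0.0496). All of these but RPS27L were named after their values were seen. RPS27L also belongs to the p53 list, whose direction it followed. Plasma cell (-0.54), granule (0.90), eosinophil and basophil (0.37), interferon-stimulated (0.41), DNA repair (-0.33), MHC class II (-0.20) and WNT pathway genes (-0.07) were not called.

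Of the 21 lists camera called 14 for H2-3 on day 2 at its preset correlation and 0 with an estimated correlation, and fry called 11. On this day 3123 genes changed, 2176 higher and 947 lower, 1729 of them at least 2-fold. The higher share of 69.7% was 80.5% with array median scaling (2488 higher, 602 lower) and 43.6% with the percentile over probes detected on all arrays (1567 and 2030), which moved the median of all genes by -0.16. Scan day and group cannot be told apart here, and no slide holds both groups. A fit with these 2 groups alone called 1602 genes, and the count was 1072, 829 or 1472 without H0 replicate 1 or H2-3 day 2 replicate 4 or 5.

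**Figure D3:**
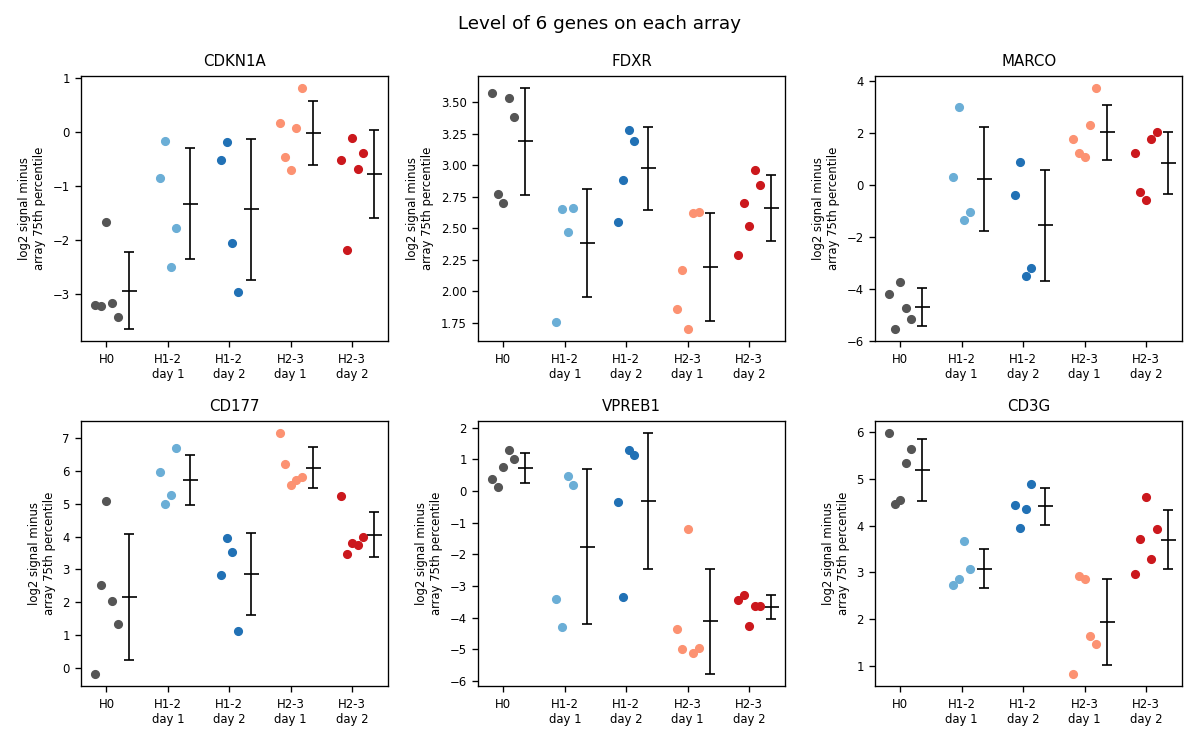
Level of CDKN1A, FDXR, MARCO, CD177, VPREB1 and CD3G (vertical axis, log2 signal minus the array's 75th percentile), with a point per array in each of the 5 groups and bars for the mean ± SD. CDKN1A was -2.94 ± 0.72 (SD, n = 5) in H0 and -0.03 ± 0.59 (n = 5) in H2-3 on day 1, while FDXR was 3.19 ± 0.42 (n = 5) and 2.20 ± 0.43 (n = 5).

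Between the HARS categories no single gene passed, and the median of the B cell list was lower in H2-3 than in H1-2 on both days, with adjusted p = 0.0436 on day 1 and 0.272 on day 2 with an estimated correlation. The mean B cell scores of H1-2 baboons 1 and 2 (0.22 and -0.03) lay near those of H2-3 (-0.98 to 0.10), and those of baboons 3 and 4 (2.42 and 2.32) above them. Camera called 14 of the 21 lists on day 1, 6 higher and 8 lower. The B cell list had a median of -2.13, with 14 of 19 members lower adjusted over the list alone and 0 over all genes. The plasma cell list had -0.84 (2 of 8 lower adjusted over the list alone) and the cell cycle list -0.51 (6 of 23 lower adjusted over the list alone). Camera called these 3 lists, with adjusted p = 0.0436 with an estimated correlation, and fry gave 0.0541 for B cell and plasma cell and 0.0591 for cell cycle genes. Camera also called naive lymphocyte (-1.44), T cell (-0.95), NK (-0.65) and monocyte genes (0.48), with adjusted p = 0.131 with an estimated correlation. The remaining calls were DNA repair (-0.20), MHC class II (-0.12), p53 (0.23), granule (0.40), inflammatory (0.24), neutrophil (0.38) and ribosomal genes (0.11), for which it gave adjusted p = 0.2 to 0.727 with an estimated correlation. On day 2 camera called 16 of the 21 lists, 8 higher and 8 lower, with adjusted p = 0.272 to 0.356 with an estimated correlation. The B cell median was -1.66 (16 of 19 lower adjusted over the list alone; adjusted p = 0.272 with an estimated correlation). Inflammatory, neutrophil, interferon-stimulated and glucocorticoid-responsive genes had medians of 0.89, 0.88, 0.62 and 0.58 (adjusted p = 0.272 with an estimated correlation). With both days averaged per baboon camera called 18 of the 21 lists, 9 higher and 9 lower, with adjusted p = 0.258 to 0.611 with an estimated correlation, and the B cell median was -1.75 (15 of 19 lower adjusted over the list alone; adjusted p = 0.258 with an estimated correlation).

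Limma called 0 genes between the categories on day 1 (1224 at an unadjusted p under 0.05), 0 on day 2 (2062) and 0 for the mean of both days per baboon (1833), and fry called 0 lists in each. By chance 1056 genes are expected at that unadjusted p in each. The shift of the B cell list was -3.39 within slide 3 and -0.29 within slide 4 on day 1, and -0.23 within slide 5 and -3.23 within slide 6 on day 2, with -1.80 and -1.57 on those days with slide as a block. Plasma cell and cell cycle medians were -1.04 and -0.66 within slide 3, -0.17 and -0.36 within slide 4, and -0.65 and -0.51 with slide as a block. For T cell markers the medians within slides 3 to 6 were -1.24, 0.27, 0.04 and -1 (with slide as a block -0.48 and -0.43). For neutrophil markers they were 0.40, 0.04, 0.06 and 1.73 (0.24 and 0.85) and for the p53 list 0.66, -0.16, -0.18 and 1.06 (0.19 and 0.35). Within slides 5 and 6 they were 0.05 and 1.89 for inflammatory, 0.42 and 0.95 for interferon-stimulated and 0.20 and 1.28 for glucocorticoid-responsive genes (0.87, 0.63 and 0.61 with slide as a block). Within slides 3 and 4 naive lymphocyte markers were at -2.73 and 0.68, NK markers at -1.36 and 0.09, monocyte markers at 0.95 and 0.02 and granule genes at 0.77 and 0.13 (-0.94, -0.54, 0.48 and 0.43 with slide as a block). There inflammatory genes were at 0.60 and -0.17, DNA repair genes at -0.23 and -0.10, MHC class II genes at 0.02 and -0.39 and ribosomal proteins at -0.13 and 0.24 (0.15, -0.27, -0.10 and 0.06 with slide as a block). Within slide 3 limma called 446 genes, within slide 4 and slide 5 0 and within slide 6 5598, and with slide as a block 0 on both days. Array weights gave 9 genes on day 1, the fit without a filter on dim probes gave 1 on day 2, and the day 1 count was 14 without H1-2 replicate 2 and 3 without H2-3 replicate 3.

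From day 1 to day 2 in H2-3, 9 of 17 T cell, 3 of 19 NK and 5 of 22 interferon-stimulated genes rose. GBP2, an interferon-induced GTPase, rose 6.71-fold (2.75 ± 0.49, adjusted p = 0.0126), and USP18, an interferon-induced protease, 5.59-fold (2.48 ± 0.38, adjusted p = 0.00805), well above background on 1 of 5 day 1 arrays (3.3-fold with the floor). The zinc finger gene ZNF462 rose 7-fold (2.81 ± 0.60, adjusted p = 0.0217) and 2.07-fold with the floor, where 1 day 1 array, the only 1 of 5 well above background, stood at -1.80 against -5.32 to -4.73 on the other 4. ADAMDEC1 fell 6.75-fold (-2.76 ± 0.68, adjusted p = 0.0392), MS4A6E 5.69-fold, with 1 day 1 array at 1.31 against -1.02 to -0.48 on the other 4, and the muscle protein gene MYOZ1 at least 1.25-fold. MS4A6E was well above background on 3 of 5 day 2 arrays (5.16-fold with the floor) and MYOZ1 on 4 of 5 day 1 arrays. Of 17 T cell markers 9 rose (13 adjusted over the list alone; median 1.67; CD3G 1.76 ± 0.39), of 19 NK markers 3 (12 adjusted over the list alone; median 1.38) and of 22 interferon-stimulated genes 5 (12 adjusted over the list alone; median 0.85; ISG15 1.13 ± 0.19). Of 18 DNA repair genes 2 rose (median 0.37). Camera called these 4 lists, with adjusted p = 0.365 with an estimated correlation, and fry called them too. The mean levels of these lists were 3.78, 2.35, 1.81 and 0.68 in H0, in the order T cell, NK, interferon-stimulated and DNA repair. In H2-3 they were 1.66, -0.09, 1.17 and 0.1 on day 1 and 2.95, 1.17, 2.1 and 0.51 on day 2. The rises therefore followed levels below H0 on day 1. USP18 and ISG15 were at -1.2 and 2.6 on day 2 against -1.23 and 2.7 in H0, and GBP2 at 3.54 against 2.87. Against H0, 0 of 22 interferon-stimulated genes passed on day 2. MZB1 rose by 2.24 ± 0.53, with -0.40 for a second probe. In the p53 list GADD45A, named after its value was seen, fell (-0.92, adjusted p = 0.0454).

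Camera also called cell cycle (0.58), eosinophil and basophil (0.97), platelet (0.80), neutrophil (-0.67) and ribosomal genes (0.13) between the days in H2-3, with adjusted p = 0.506, 0.506, 0.634, 0.64 and 0.735 with an estimated correlation. With the baboon as a paired block 15 lists were called. The 6 further lists were p53, B cell, monocyte, granule, erythroid and inflammatory genes with adjusted p = 0.0315, 0.0316, 0.0198, 0.00249, 0.0315 and 0.00144. With the block and an estimated correlation 0 lists were called, and these 15 had adjusted p = 0.384 to 0.585. In all 628 genes changed in the main fit, which leaves out the pairing of the days, 368 higher and 260 lower. The higher share of 58.6% was 71.6% with array median scaling (434 and 172), 72.9% with normexp (204 and 76) and 74.7% with the percentile over probes detected on all arrays (242 and 82). Array weights gave 4316 genes, the baboon as a random block 3406, slide as a random block 225 and a fit with these 2 groups alone 167. Without day 1 replicate 1, 3, 4 or 5 the count was 286, 290, 83 or 140, and without day 2 replicate 1, 2, 3, 4 or 5 it was 3734, 189, 90, 139 or 22; scan day and day cannot be told apart.

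From day 1 to day 2 in H1-2, limma called 0 genes in the main fit, with 4957 at an unadjusted p under 0.05, against 1056 expected by chance. That fit leaves out the pairing of the days, and with the baboon as a random block limma called 902. Neutrophil markers had a median of -1.10 (9 of 21 lower adjusted over the list alone) and inflammatory genes -1 (4 of 20 lower adjusted over the list alone). The medians were 1.11 for T cell markers (6 of 17 higher adjusted over the list alone), 1.09 for NK markers, 0.97 for platelet genes, -0.76 for granule genes, 0.62 for ribosomal proteins and 0.38 for DNA repair genes. Camera called these 8 lists, with adjusted p = 0.53 for each with an estimated correlation, and fry called 0. Without day 2 replicate 1 camera called 13 lists. With the baboon as a paired block 0 genes and 13 lists were called. The 5 further lists were p53, naive lymphocyte, eosinophil and basophil, interferon-stimulated and glucocorticoid-responsive genes with adjusted p = 0.042, 0.00621, 0.00626, 0.0224 and 0.0345. With the block and an estimated correlation 0 lists were called, and these 13 had adjusted p = 0.434 to 0.594. Normexp gave 4 genes, no filter 5, the deposited values 19, array weights 2433 and the baboon as a random block 902. The count was 1 without day 1 replicate 2 or 3 or day 2 replicate 1, 181 without day 2 replicate 2 and 73 without day 2 replicate 3.

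Whether the change between the days differed between the categories was tested as an interaction, for which limma called 0 genes and fry 0 lists. At an unadjusted p under 0.05 there were 421 genes, against 1056 expected by chance. Camera called 7 lists, with interferon-stimulated genes (median difference 0.67) and ribosomal proteins (-0.45) having the smallest adjusted p, 4.9e-08 and 1.07e-23, and 0.425 with an estimated correlation. With slide as a block limma called 0 genes and the medians were 0.58 and -0.36. With the baboon as a paired block limma called 0 genes and camera 7 lists, and these left out plasma cell markers (adjusted p = 0.0532) and took in T cell markers (adjusted p = 0.0292). With the block and an estimated correlation 0 lists were called, and these 7 had adjusted p = 0.558 to 0.756. Camera called 11 lists without H2-3 day 1 replicate 3 and 3 without H2-3 day 2 replicate 5.

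The comparisons with H0 share the 5 H0 arrays, so their calls overlap by chance. Of the genes called on day 1 in H1-2, 849 rose and 886 fell on day 1 in H2-3 as well, against 132 and 126 for independent lists and 0 and 0.02 for simulated unchanged groups. Almost no gene passes in unchanged groups, so the last 2 values were bound to be near 0. They do not measure how far the shared arrays raise the overlap. Across genes, which are not independent replicates, the changes correlated at 0.88 (simulated 0.47), with a covariance of 0.45 (simulated 0.06). With the H0 arrays split between the comparisons, the overlaps were 0 to 610 and 0 to 582 and the correlation 0.57 to 0.75. Between days 1 and 2 in H2-3, 1653 genes rose and 618 fell on both, against 326 and 128 for independent lists, with a correlation of 0.71 (simulated 0.50) and a covariance of 0.41 (simulated 0.06). With the H0 arrays split there were 1 to 834 and 0 to 358 genes and a correlation of 0.35 to 0.71. In H1-2 the changes on the 2 days correlated at 0.44 (simulated 0.44), with a covariance of 0.13 (simulated 0.06) and a correlation of -0.08 to 0.46 with the H0 arrays split. Those simulations drew every array independently, although both days hold the same baboons. With the arrays of a baboon correlated at 0.252, a simulation chosen after seeing the data, the simulated correlation was 0.63 in H2-3 and 0.59 in H1-2 between the days, and the covariance 0.08 in both.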

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

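The tests of the interaction and of single values far from their group were set before the data were examined. In 510 groups of 4 or 5 values, the gap between the farthest value and its neighbour was divided by the range of the group; 31 groups passed Dixon's critical value, 27 for genes and 4 for gene lists, against 26 expected by chance. H0 replicate 3 stood apart 5 times. Of the 27 gene groups 2 (ID1 in H0 and MTX3 in H1-2 on day 1) had no array well above background, so their gaps lie between background values. Another 4 had 1 such array (CDKN1A and UNC45B in H0, VPREB1 and ZNF462 in H2-3 on day 1). All values are log2 signals relative to the array's 75th percentile.

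In H0, replicate 3 had AEN at -5.13 against -3.1 to -2.37 on the other 4 arrays (ratio 0.734) and CCR7 at 4.45 against 6.29 to 6.59 (0.861). It also had CDKN1A at -1.67 against -3.43 to -3.17 (0.854), TMEM44 at 1.93 against -2.21 to -1.07 (0.725) and UNC45B at -2.58 against -5.49 to -4.76 (0.75). H0 replicate 1 had CD163 at 3.38 against 5 to 5.62 (0.726), FCAR at -0.77 against 1.53 to 2.42 (0.721) and immediate early and heat shock genes at 0.69 against 1.55 to 1.89 (0.718). H0 replicate 2 had ID1 at -4.03 against -5.51 to -5.13 (0.739), and H0 replicate 5 had WNT pathway genes at 0.5 against 0.71 to 0.79 (0.723).

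In H1-2 on day 1, TMEM44 was at 2.84 in replicate 1 against 2.07 to 2.15 in the other 3 (0.895), TSC22D3 at 7.8 in replicate 2 against 8.16 to 8.19 (0.932) and ZNF462 at -3.98 in replicate 2 against -1.84 to -1.52 (0.869). In replicate 3 MTX3 was at -3.38 against -5.23 to -4.94 (0.843) and SLC26A9 at -2.57 against -1.52 to -1.32 (0.843). On day 2 in H1-2, GBP2 was at 2.96 in replicate 2 against 1.36 to 1.45 (0.944), interferon-stimulated genes at 1.92 in replicate 2 against 1.24 to 1.33 (0.863), and plasma cell markers at 2.39 in replicate 3 against 1.36 to 1.49 (0.872).

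In H2-3 on day 1, replicate 1 had CCR3 at 1.18 against 2.36 to 2.71 (0.768), MS4A6E at 1.31 against -1.02 to -0.48 (0.77) and MYOZ1 at -4.6 against -2.9 to -2.25 (0.724). Replicate 2 had WLS at 2.66 against 4.33 to 4.8 (0.783) and ZNF462 at -1.8 against -5.32 to -4.73 (0.832). Replicate 3 had TMEM44 at -2.22 against 2.01 to 2.67 (0.866) and VPREB1 at -1.19 against -5.12 to -4.36 (0.807). Replicate 4 had FOSB at -2.04 against -1.21 to -0.91 (0.74). On day 2 in H2-3, replicate 1 had CD177 at 5.25 against 3.48 to 3.99 (0.715) and ISG15 at 3.1 against 2.34 to 2.54 (0.743). Replicate 2 had CDKN1A at -2.19 against -0.68 to -0.12 (0.731), MDM2 at 2.47 against 2.99 to 3.11 (0.81) and WLS at 2.33 against 4.28 to 4.87 (0.77).

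The change from day 1 to day 2 differed between the categories by camera's interaction test for 7 lists, none of them kept with an estimated correlation. The median differences were 0.33 for plasma cell markers (adjusted p = 0.0337, and 0.425 with an estimated correlation), 0.48 for mature neutrophil markers (0.00657, and 0.924), 0.67 for interferon-stimulated genes (4.9e-08, and 0.425). They were 0.59 for innate inflammatory genes (0.0026, and 0.924), 0.56 for glucocorticoid-responsive genes (0.0193, and 0.732), 0.37 for cell cycle genes (0.0095, and 0.924) and -0.45 for ribosomal proteins (1.07e-23, and 0.425). With slide as a block these medians were 0.21, 0.50, 0.58, 0.62, 0.56, 0.30 and -0.36. Limma called 0 genes for the interaction, with 421 at an unadjusted p under 0.05 against 1056 expected by chance, and fry called 0 lists.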

How the results depend on the processing

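Fits within single slides, the percentile over probes detected on all arrays and the replicate block with an estimated correlation were chosen after seeing the data; the other settings were planned. Of 122 called gene results, 52 were called under every alternative with a value and 0 reversed. Leaving out single arrays, the numbers of genes ranged from 4 to 3105 for H1-2 day 1 against H0, 0 to 6 for H1-2 day 2, 4869 to 6533 for H2-3 day 1, 829 to 4387 for H2-3 day 2. They ranged from 0 to 14 and 0 to 0 for H2-3 against H1-2 on days 1 and 2, 0 to 181 and 22 to 3734 for day 2 against day 1 in H1-2 and H2-3, and 0 to 0 for the interaction and for the mean per baboon. The numbers of lists ranged, in the same order, from 9 to 16, 4 to 11, 13 to 17, 13 to 16, 11 to 16, 13 to 17, 9 to 13, 7 to 13, 3 to 11 and 16 to 19. Counts of lists moved by over 1.5 times without H1-2 day 1 replicate 2 for H1-2 day 1 (9), without H0 replicate 1 or 5 or H1-2 day 2 replicate 1 or 2 for H1-2 day 2 (6, 4, 4 and 5), without H1-2 day 2 replicate 1 for the days in H1-2 (13), and without H2-3 day 1 replicate 3 or day 2 replicate 5 for the interaction (11 and 3).

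For H1-2 day 1 against H0, 9 genes passed with slide as a fixed block, 4 with scan day as a block, 211 with the compared groups alone and 0 with the replicate block. Whether an H0 baboon and an irradiated baboon of the same number are the same animal is not given. Their deviations correlated at -0.33 to 0.09 for H1-2 day 1 and -0.32 to 0.22 for H1-2 day 2. For H2-3 the values were -0.15 to 0.01 on day 1 and -0.08 to 0.51 on day 2. Different numbers gave means of 0.03, 0.01, 0.01 and -0.06 in that order. Array weights gave 33 genes for H1-2 day 2. For H2-3 day 1, slide as a fixed block gave 1112 and slide 1 alone 2347, both from 1 array against 1 with the spread of the other arrays, and for H2-3 day 2 the compared groups alone gave 1602. Between the categories, array weights gave 9 and slide 3 alone 446 on day 1, and no filter on dim probes gave 1 and slide 6 alone 5598 on day 2. For day 2 against day 1, normexp gave 4, no filter 5, the deposited values 19, array weights 2433 and the baboon as a random block 902 genes in H1-2. In H2-3 normexp gave 280, the percentile over probes detected on all arrays 324, array weights 4316, the baboon as a random block 3406, slide as a random block 225 and the compared groups alone 167. The cause was not tested. Single slides and the compared groups alone hold fewer samples, which would not by itself raise a count as on slides 3 and 6. Those 2 slides hold H1-2 baboons 3 and 4, and slides 4 and 5 hold H1-2 baboons 1 and 2.

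With an estimated correlation, camera called 3 lists for H2-3 against H1-2 on day 1 and 0 in the other 9 comparisons. Against H0, fry called 15 lists for H2-3 day 1, 11 for H2-3 day 2, 8 for H1-2 day 1 and 0 for H1-2 day 2. It called 4 for day 2 against day 1 in H2-3 and 0 for day 2 against day 1 in H1-2. For both comparisons between categories, their mean and the interaction it called 0. With the replicate block camera called 6 lists for H1-2 day 2, 13 for the days in H1-2 and 15 for the days in H2-3; in the day comparisons it changed no call of a named gene. With the replicate block and an estimated correlation camera called 0 lists for the days in H1-2, 0 for the days in H2-3 and 0 for the interaction. IFIT1B reversed between the categories on day 2 within slide 6 (-1.72). The direction reversed without an array for ribosomal proteins between the categories on day 1 (adjusted p = 0.762 without H1-2 day 1 replicate 1; lowest to highest 7.14e-06 to 0.762). It did so for erythroid genes in the interaction (0.0178 without H1-2 day 2 replicate 3; 0.0178 to 0.999) and platelet genes between the categories on day 2 (0.00308 without H1-2 day 2 replicate 4; 0.00308 to 0.987). The cause was not tested. Array median scaling moved the median of all genes by 0.12 for the days in H1-2, and the percentile over probes detected on all arrays moved it by -0.12, -0.19 and -0.16 for H1-2 day 1, H2-3 day 1 and H2-3 day 2 against H0 and by -0.11 between the categories on day 2. Signal well above background on 41.4 to 51.3% of the probes limits what could be measured.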

Other observations

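The tests of H1-2 baboons 1 and 2 against 3 and 4 and of the other pairs, of FDXR under other scalings and of other FDXR probes were chosen after the result was seen, and so were the test of the B cell list with categories permuted within slides and the 3 patterns weighed here. The test of the B cell medians within slides was written after the gene counts within slides were seen, but before its medians were.

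In other splits of the same arrays, limma called as many genes as between H1-2 day 1 and H0 (1816) in 2 of 100 splits, the real one included; the other, with 2934 genes, placed H0 replicate 3 with H1-2 arrays. The share is under the 0.05 set beforehand, which argues against chance as the whole source of the count. It does not exclude chance, since the count fell to 4 without H1-2 day 1 replicate 1. For H2-3 against H0 on day 1 (6007 genes, highest other 2532) and on day 2 (3123, highest other 1917), 1 of 100 splits gave as many. This argues against chance as the whole source of those counts. For day 2 against day 1 in H2-3 (628 genes), 1 of 100 splits made without regard to the pairs gave as many (highest other 298), but the arrays are paired by baboon. The 16 splits that part all pairs are too few for a share under 0.05, with 628 genes in the real one and at most 16 in the others, whereas the remaining splits leave both days of some baboons on one side. With a count of 0 every split gives at least as many, so these splits say nothing about chance. They were 100 of 100 for H1-2 day 2 against H0 (highest other 319), for H2-3 against H1-2 on day 1 (3) and day 2 (1134), for the interaction (10) and for the mean per baboon (7). They were 35 of 35 for day 2 against day 1 in H1-2 (1536; 3 among the 8 splits that part all pairs). The split with 1536 genes set H1-2 baboons 1 and 2 against 3 and 4, which also lay on different slides, and such counts point to a structure of the samples.

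In H1-2, baboons 1 and 2 stood apart from 3 and 4, and a slide effect is argued against as the whole source. The difference between slides in H1-2 correlated with that of the H2-3 arrays on the same slides at 0.03 on day 1 and -0.3 on day 2, across genes, which are not independent replicates. The H1-2 difference on day 1 correlated with that on day 2, measured on other slides and another scan day, at 0.65, against -0.31 and -0.34 for the other ways to part these baboons into pairs and 0.34 for the H2-3 arrays on the same slides. The split of both days' arrays into these pairs gave 1536 genes, the most of any split, and such a count already asks for agreement between the days. The 0.65 is therefore not independent of that count, and a lasting difference between the baboons stays a hypothesis. The H2-3 value of 0.34 also passed the bound of 0.3 set for a lasting difference. Dose and total or partial irradiation per animal were not analysed here and stay open.

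B cell markers were lower in H2-3 than in H1-2, with mean scores per baboon of -0.56 ± 0.4 (SD, n = 5) and 1.23 ± 1.32 (SD, n = 4), and an exact two-sided permutation p of 0.0159 over 126 splits. The score fell further than that of T cell markers by 1.17 on the log2 scale (exact permutation p = 0.0476), and by 1.26 further than that of NK markers (0.0794, adjusted 0.119). Neutrophil and monocyte scores were 0.56 and 0.45 higher in H2-3 (0.0476 and 0.0317, both adjusted 0.107). The B cell score and its difference from T cells met bounds written beforehand, but those bounds took no account of the 9 scores tested; adjusted over the 9, both are 0.107, so neither chance nor dilution is excluded, a decision made after the values were seen. Within slides 3 to 6 the median shift was -3.39, -0.29, -0.23 and -3.23, the value nearest to 0 being -0.23, and limma called 14, 0, 0 and 19 of the 19 members lower. A slide effect shared by both categories leaves no shift within a slide other than that between the baboons on it. With slide as a block the shift of the score on day 2 was -1.54, with an exact two-sided permutation p of 0.117 over 60 arrangements of the categories within slides, so a slide effect together with chance between few baboons stays open. On day 1 the 36 arrangements cannot give a p under 0.0556. Related versions on the mean per baboon were worked out roughly before the day 2 version was chosen. They gave lower p-values and are not reported as tests, so the choice of version bears on this p. The H1-2 scores were 0.22, -0.03, 2.42 and 2.32 in baboons 1 to 4 and those in H2-3 -0.75, -0.60, 0.10, -0.98 and -0.56, so the difference rests on H1-2 baboons 3 and 4.

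FDXR was lower on day 1 in H2-3 than in H0 while the p53 targets CDKN1A, DDB2 and AEN were higher. FDXR was not alone in the p53 list, since PLK2 (-1.93) and POLH (-0.95) were lower as well, and BAX and PCNA did not pass. Scaling is excluded as the whole source, since under 5 other scalings or background corrections the log2 change of FDXR was -1.18 to -0.93. Scan day is excluded likewise, with -1.01 (unadjusted p = 0.00205 by limma) with scan day as a block. A slide effect stays open, since only slide 1 holds both groups, with 1 array of each. That the human probe may misread the baboon transcript stays open, since there were 0 other FDXR probes on the array. A change in the mix of blood cells was not tested.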
